A study of Arabidopsis thaliana with 6 samples.

How the data were processed

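RNA from whole seeds of 6 samples, 3 of the pmdh1 pmdh2 double mutant and 3 of the wild-type segregant, was labelled with biotin and hybridised to 1 array each, per the labels. Groups and replicate numbers were taken from the sample labels. The deposited values are probe-set intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the probes of a set into a signal and scales each array by 1 factor. From the values, the mean signal without the lowest and highest 2% of probe sets was 100.0 on every array, so arrays share a mean but not a distribution. MAS5 subtracts mismatch probes, which makes signals near background noisy. Detection calls were not used here.

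Signals were transformed as log2(signal + 10), the pseudocount being 10% of the trimmed mean. Between 24.1% and 27.0% of probe sets on an array had signals under the pseudocount. The 64 control probe sets were left out, and the 13648 of the other 22746 whose mean log2 value lay at or above the 40th percentile were tested, a floor of 5.02. Tests used limma 3.58.1 in R 4.3.3, with statmod 1.5.0 installed, fitting mutant minus wild type over all 6 arrays with no covariate and eBayes with an intensity trend (prior degrees of freedom 11.5). Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. An SE beside a log2 fold change is limma's moderated one.

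Genes were named from the platform annotation supplied with the values and updated through gene identifiers to the TAIR10.1 annotation, which matched 13436 of 13513 probe sets naming 1 gene. A further 503 probe sets name several genes and 8730 are unnamed here, which does not mean that they lack a gene. Of the probe sets tested, 7331 name 1 gene, and 67 loci had more than 1 tested probe set, 0 of them with calls in opposite directions. The deposited values name no genome build, so no coordinates are given. Many genes with long-established symbols, PMDH1 and PMDH2 among them, fall among the unnamed, so those lists were measured only in part and the planned check of the disrupted genes was not run.

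The comparison, its test, the named-gene rule, 19 gene lists and the alternatives were fixed before the data were examined. The rule names every measured malate dehydrogenase, the 10 largest increases and 10 largest decreases among called probe sets that name 1 gene and whose groups do not overlap, and in each list up to 4 members with the smallest p. Genes named outside it are said to be. A list member was matched by locus and represented by its brightest probe set. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 6 lists tested. The lists covered the disrupted genes, other malate dehydrogenases, lipid mobilisation and peroxisomal beta-oxidation, the glyoxylate cycle, the tricarboxylic acid cycle, photorespiration, photosynthesis, seed maturation, abscisic acid, gibberellin, sugar starvation, anthocyanin, antioxidant, jasmonate, peroxisome biogenesis, heat shock, dividing cell, root hair and endosperm genes. A further 3 lists were added after the data were seen, as were a test of the hypoxia list without its most lowered genes, the median of the plastid-encoded probe sets within the range of signal of the mitochondria-encoded ones, and a bound for genes with all signals of a group under the pseudocount. Array measures were compared by exact permutation tests, which cannot go below 0.1 with 3 arrays against 3, and calls near the disrupted loci by Fisher's exact test.

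The fit and the list test were tested on simulated data made for this comparison with its 13648 probe sets, 20 runs of 200 changed genes each. Recovery was 43.4% of genes changed by 0.5 on the log2 scale, 97.9% of those changed by 1 and 100% of those changed by 2, and 7.12% of calls were false. Without any change the mean was 0.45 calls per run. Camera gave p under 0.05 for 3.4% of unshifted lists of 10 genes and for all 20 lists shifted by 0.5. Simulated errors were normal, with the variances that the fit itself had moderated. Recovery and false calls therefore do not check that moderation and may be too favourable. The simulated probe sets also varied independently of each other. In the data, estimated correlations were 0.37, 0.42 and 0.21 for the seed, photosynthesis and photorespiration lists. These rates therefore do not show camera's errors for lists of correlated genes. Alternatives were no and a doubled pseudocount, no and a stricter filter, quantile normalization, median centring, eBayes without the trend or robust, a replicate block, only probe sets naming 1 gene, ordinary t statistics, the mean of a locus's probe sets, and leaving out each array in turn.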

Results

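Whole germinating seeds of Arabidopsis thaliana were profiled on ATH1 arrays, 1-colour arrays on which several short probes per transcript are combined into 1 value per probe set. There were 6 arrays, 3 of a double mutant with T-DNA insertions in both genes for peroxisomal malate dehydrogenase and 3 of wild-type plants that segregated from an insertion heterozygote. Seeds were stratified for 2 days at 4 °C and grown in continuous light at 22 °C on agar with 1% sucrose, and were taken at growth stage 0.7, when hypocotyl and cotyledons emerge from the seed coat. The deposited values were MAS5 signals for 22810 probe sets, 64 of them controls. Each array had a trimmed mean signal close to 100, and median signals were 38.5 ± 0.693 (SD, n = 3) in the mutant and 35.6 ± 1.26 (SD, n = 3) in the wild type. Nothing in the labels says whether replicates came from separate plants or batches of seed, so p-values measure the spread between these samples, which may be partly technical. The number of arrays, 3 per group, limits the precision of every value.

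The comparison asked which transcripts differ in germinating seeds that lack peroxisomal malate dehydrogenase, the enzyme that exchanges malate and oxaloacetate in peroxisomes and so reoxidises the NADH formed there by fatty acid beta-oxidation. The disrupted genes, PMDH1 (AT2G22780) and PMDH2 (AT5G09660), have no probe set named for them in the probe annotation used here. Their transcripts were therefore not analysed here, and the genotype labels were not checked against them. Of the other malate dehydrogenases, MDH (AT3G47520), the plastid NAD-dependent form, had a log2 fold change (mutant minus wild type) of −0.16 (SE 0.11, limma adjusted p = 0.52). AT5G58330, the NADP-dependent chloroplast form, had a change of −0.35 (SE 0.10, adjusted p = 0.079), which passed when adjusted over the list alone and, over all probe sets, after median centring of the arrays or without wild-type replicate 1 (−0.42).

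Transcripts of seed storage and late embryogenesis abundant (LEA) proteins were among the 10 largest increases in the double mutant among probe sets that name 1 gene. M17, a LEA family gene of late seed development, had signals of 139 to 171 in the mutant arrays and 0.22 to 6.09 in the wild-type arrays. All its wild-type signals lay under the pseudocount of 10, so the size of its fitted log2 fold change (3.69, SE 0.19) depends on the pseudocount. With each wild-type signal set at the pseudocount it was at least 8.14-fold higher. PAP85, a vicilin-like storage protein gene, was 9.57-fold higher (3.26, SE 0.17). AT1G04560, AT1G54870 and LEA18 were 7.70-fold, 7.32-fold and 6.23-fold higher, LCR67, which encodes a plant defensin, 5.63-fold, and AT3G54940 5.23-fold. AtLEA4-1, AT3G17520, a LEA family gene, and AT2G21820 completed the 10 largest increases among probe sets that name 1 gene, at 5.11-fold, 4.92-fold and 4.04-fold. Adjusted p-values of these 10 lay between 1.29e-08 and 0.000648, and no mutant value overlapped a wild-type value. The naming rule required both a call and no overlap. The wild-type signal of AT3G17520 was 1.00 in replicate 3 and 25.6 and 27.6 in the others. Without a pseudocount M17 fell below the filter, and log2 fold changes were larger by over 1.5 times in fold for PAP85 (3.97), AT3G17520 (3.63), AT1G54870 (3.53) and AT2G21820 (2.63), so the order of these genes depends on the pseudocount.

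The 10 largest decreases among probe sets that name 1 gene included AT3G10040, a trihelix transcription factor gene known to be induced by low oxygen, which was 5.63-fold lower in the mutant (log2 fold change −2.49, SE 0.15). AT1G33055 was 5.38-fold lower (−2.43, SE 0.16) and CML38, which encodes a calmodulin-like protein, 4.87-fold lower (−2.28, SE 0.20). AT5G66985, AT3G27220, a kelch-repeat gene, and AT2G17850, a rhodanese-like gene, were 4.56-fold, 4.49-fold and 4.14-fold lower. AT4G33560, AT4G10270, AT5G26200 and AT4G24110 were 3.94-fold, 3.79-fold, 3.27-fold and 3.14-fold lower. Adjusted p-values of these 10 lay between 4.72e-08 and 0.0027, again with no overlap between groups, which the naming rule required. AT5G26200 had a signal of 1.79 in mutant replicate 2 against 20.8 and 21.4 in the other mutant arrays, and lost its call when dim probe sets were not filtered out. Without a pseudocount CML38 (−2.93) and AT5G26200 (−2.77) were lower by over 1.5 times more in fold, and the order changed. All fold changes are on the log2(signal + 10) scale, which understates changes of transcripts with low signal.

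**Figure D1:**
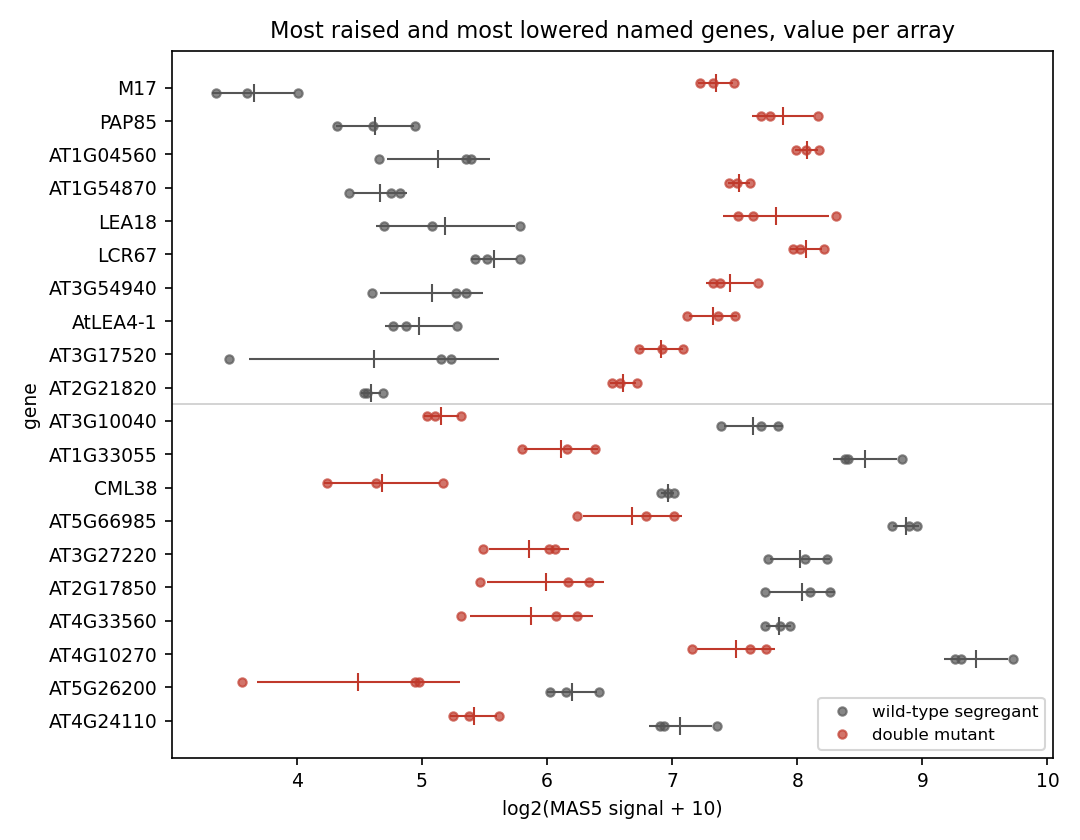
Values of the 10 most raised and 10 most lowered named genes as log2(MAS5 signal + 10), 1 point per array, with grey points for the 3 wild-type arrays and red points for the 3 mutant arrays. The vertical tick is the group mean and the horizontal line 1 SD to each side. In no gene do the points of the groups overlap, which the rule for naming them required.

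Over all 13648 probe sets tested, 516 (3.78%) differed between the genotypes at an adjusted p under 0.05 in limma, 267 higher and 249 lower in the mutant. A change of at least 2-fold was seen for 109 of them, 68 higher and 41 lower, and a change of at least 4-fold for 21 higher and 8 lower. Of the 516, 238 name 1 gene (107 higher, 131 lower), 10 name several genes and 268 are unnamed in the annotation used here (154 higher, 114 lower). Values of the groups did not overlap for 21.9% of the probe sets tested, where chance gives 10% on average over splits. Probe sets share the same arrays, so the excess over 10% was not tested. Median log2 values were higher in every mutant array (5.57 to 5.61) than in any wild-type array (5.46 to 5.54), and such a shift can raise this share. With each array centred on its median, 625 were called and 30.2% of these were higher, against 51.7% at the deposited scaling. The count was 228 without the filter on dim probe sets, 325 without the intensity trend in the variance and 12 with ordinary t statistics, and it was 343, 274 and 321 without mutant replicate 1, 2 or 3 and 284 without wild-type replicate 3.

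**Figure D2:**
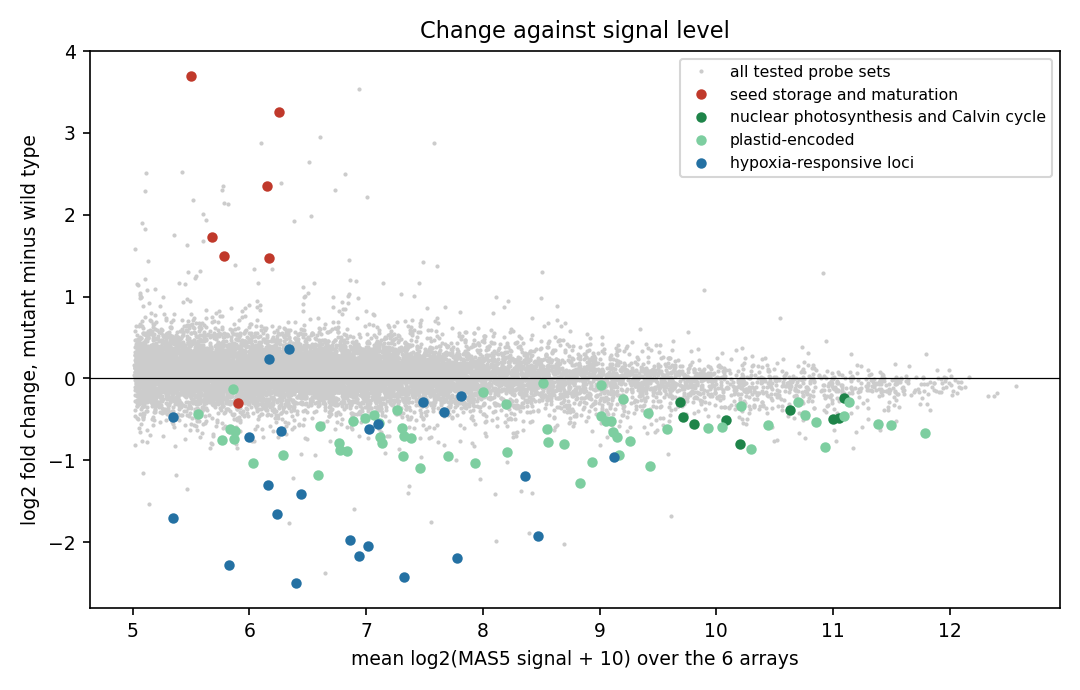
Log2 fold change (mutant minus wild type) against the mean log2(MAS5 signal + 10) over the 6 arrays, 1 grey point per tested probe set. Coloured points are members of the seed storage and maturation list (red, 6 of 7 higher), the nuclear photosynthesis and Calvin cycle list (dark green, 6 of 9 lower), plastid-encoded genes (light green, 34 of 62 lower) and hypoxia-responsive loci (blue, 17 of 24 lower), the last 2 lists having been chosen after the data were seen.

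Pathways and cell types were followed with 19 gene lists holding 370 genes. Of these genes 74 had a named probe set and 68 passed the filter, so each list was measured only in part, and 6 lists had the 5 members needed for a list test.

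Most measured seed storage and maturation genes were higher in the mutant, while the call of the list depended on the correlation assumed between genes. Of the 7 members tested, out of 35 listed, 6 were higher, and the same number was higher when adjusted over the list alone. They included M17, PAP85, AtLEA4-1 and AT3G01570, an oleosin family gene (log2 fold change 1.49, SE 0.17, adjusted p = 4.61e-05). The exception was OLEO3, an oleosin gene named here after its value was seen, at −0.30 (SE 0.14, adjusted p = 0.31). The median log2 fold change of the list was 1.73, and limma's camera gave an adjusted p of 5.56e-14 with a preset correlation and an adjusted p = 0.0665 with an estimated correlation. This list also marks the late embryo stage, and its mean log2 value was 6.90 ± 0.110 (SD, n = 3) in mutant and 4.94 ± 0.287 (SD, n = 3) in wild-type arrays.

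Of the measured nuclear genes of photosynthesis and the Calvin cycle, most were lower in the mutant, and here too the call of the list depended on the correlation assumed. Of the 9 members tested, out of 44 listed, 6 were lower and 3 did not pass, and all 9 were lower when adjusted over the list alone. LHCB4.2, a light-harvesting protein gene, changed by −0.80 (SE 0.11, adjusted p = 0.00039) and PSAN, a photosystem I subunit gene, by −0.56 (SE 0.10, adjusted p = 0.00515). RCA, the gene of rubisco activase, changed by −0.49 (SE 0.092, adjusted p = 0.00613) and LHCB4.1 by −0.50 (SE 0.11, adjusted p = 0.013). PSBY, PRK and PSAE-1, named after their values were seen, did not pass, at −0.39, −0.29 and −0.23. PSBY passed after median centring, and PSBY (−0.52) and PRK (−0.43) passed without wild-type replicate 1. The median was −0.49, with a camera adjusted p of 4.56e-12 and an adjusted p = 0.0736 with an estimated correlation. The call of RCA was lost without the filter or without the intensity trend. That of LHCB4.1 was lost in both settings, under quantile normalization, and without mutant replicate 2 (−0.38) or wild-type replicate 2 (−0.47).

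The photorespiration list had a negative median. Of 5 members tested, out of 21 listed, HPR, which encodes peroxisomal hydroxypyruvate reductase, was lower at −0.54 (SE 0.13, adjusted p = 0.034), and 3 were lower when adjusted over the list alone. AT1G80380, AT1G11860, LrgB and AT1G79870, the last named after its value was seen, did not pass over all probe sets, at −0.34, −0.33, −0.32 and −0.11. AT1G11860 (−0.43) and LrgB (−0.53) passed without wild-type replicate 1, and AT1G11860 also after median centring. The median was −0.33, with a camera adjusted p of 0.000577 and an adjusted p = 0.106 with an estimated correlation. The call of HPR was lost without the filter, without the intensity trend, under quantile normalization, and without mutant replicate 2 (−0.44) or 3 (−0.52) or wild-type replicate 2 (−0.49) or 3 (−0.47). With limma's fry, which does not compare a list with other genes, adjusted p-values were 0.00148 for the seed list, 0.0147 for photosynthesis and 0.0536 for photorespiration.

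The other lists large enough to test did not pass with camera (adjusted p = 0.99 for each). None of the 11 tricarboxylic acid cycle and pyruvate dehydrogenase members passed in limma, and 0 had an unadjusted p under 0.05, with changes from −0.28 for SDH2-2 to 0.19 for SDH1-1, including 0.16 for IDH-VI and 0.18 for AT3G55410. None of the 5 gibberellin and cell expansion members passed and 1 had an unadjusted p under 0.05, EXPA8 at 0.47, which passed without wild-type replicate 1 (0.64). GID1A, CP1 and GID1B were at −0.14, 0.05 and −0.02, and GID1C, named after its value was seen, at −0.01. None of the 6 sugar starvation members passed and 1 had an unadjusted p under 0.05, IVD at 0.37, with MCCB at −0.19, MCCA at 0.15 and ETFQO at −0.14. Median, mean and camera direction differed in sign for these lists. The medians were 0.07, −0.01 and 0.01, the means 0.03, 0.07 and 0.03, and camera's directions down, up and down relative to the other probe sets. Ordinary t statistics called 0 members of any list, the lists with limma calls included.

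Few genes of the list for lipid mobilisation and peroxisomal beta-oxidation were measured. SDP1, the gene of the main oil body lipase, SDP1-LIKE, OPCL1 and AIM1 changed by 0.14, 0.13, 0.11 and 0.04, none passing in limma and 0 at an unadjusted p under 0.05, and AIM1 was negative at −0.03 after median centring. ICL, which encodes isocitrate lyase of the glyoxylate cycle, changed by −0.04 (SE 0.090, adjusted p = 0.86) and by 0.05 under quantile normalization. Its signals were 4183 to 4370 in the mutant and 3891 to 4796 in the wild type. PPDK, whose product makes phosphoenolpyruvate from pyruvate, changed by 0.38 (SE 0.11, adjusted p = 0.076) and passed when adjusted over the list alone and without wild-type replicate 1 (0.45).

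Among stress and hormone lists, COR47, a dehydrin gene responsive to abscisic acid, was 1.98-fold higher (log2 fold change 0.99, SE 0.18, adjusted p = 0.00528), a call lost without the filter, while the probe set shared by KIN1 and KIN2 changed by 0.03. GSTU25, a glutathione transferase gene, was 1.83-fold higher (0.87, SE 0.13, adjusted p = 0.000768), and NDB2 and AT2G21640 did not pass, at 0.31 and 0.24. AT5G51440, a small heat shock protein gene, was 1.53-fold lower (−0.62, SE 0.13, adjusted p = 0.0114), a call lost without mutant replicate 1 (−0.59) or wild-type replicate 3 (−0.58), and AT5G37670 did not pass, at −0.42. When adjusted over the list alone, 1 of the 2 abscisic acid probe sets, 1 of the 3 antioxidant genes and both heat shock genes passed. The anthocyanin genes UF3GT, DFR and AT4G14090 changed by 0.45, 0.42 and 0.04, with 0 passing in limma over all probe sets, 2 at an unadjusted p under 0.05 and 2 when adjusted over the list alone. PEX4 and BIGYIN, the peroxisome biogenesis genes measured, did not pass, at −0.13 and 0.12 (limma adjusted p = 0.60 and 0.69). None of these lists had enough members for a list test, and 0 members of the jasmonate and endosperm lists were tested.

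No measured marker of other cell types passed. HTR12, PRL and AUR1, genes of dividing cells, changed by 0.20, 0.04 and −0.06, and EXPA7 and EXPA18, genes of root hair cells, by −0.13 and 0.04. In limma 0 had an unadjusted p under 0.05, and PRL and EXPA18 were each at −0.03 after median centring.

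**Figure D3:**
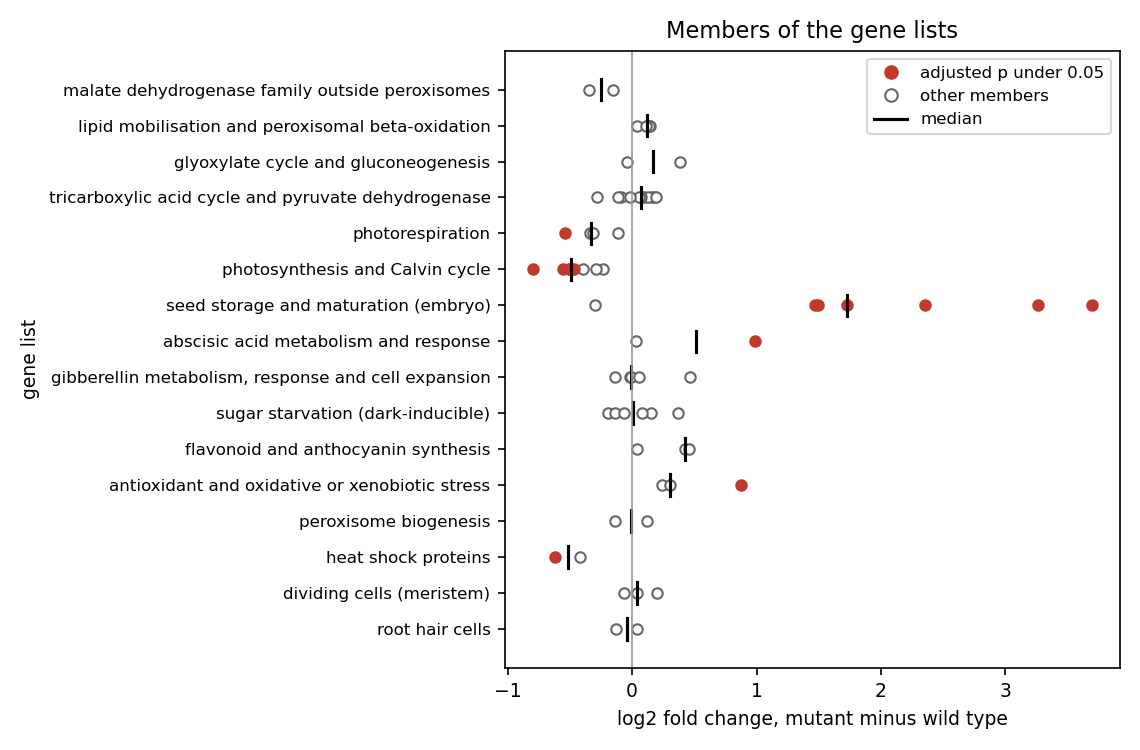
Log2 fold change (mutant minus wild type) of each tested member of the gene lists, filled red where the adjusted p over all probe sets was under 0.05 and open grey otherwise, with a black bar at the list's median. In the seed storage and maturation list 6 of 7 members lie to the right of 0 and in the photosynthesis and Calvin cycle list all 9 lie to the left, 6 of them passing.

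Control ratios that follow RNA degradation overlapped between the genotypes. The log2 ratio of 3′ to 5′ control signal for actin was 0.607 ± 0.0803 (SD, n = 3) in the mutant and 0.728 ± 0.140 (SD, n = 3) in the wild type (exact two-sided permutation p = 0.3). The ratios for GAPDH were −0.145 ± 0.0656 and −0.0473 ± 0.110 (SD, n = 3 each, exact p = 0.3) and for ubiquitin 0.134 ± 0.137 and 0.291 ± 0.0892 (SD, n = 3 each, exact p = 0.2). The median log2 value was higher in the mutant by 0.0883, with the smallest exact p that 3 against 3 allows, 0.1. Over all probe sets, correlations between arrays of 1 group were 0.977 to 0.984, and between groups 0.972 to 0.978, across genes, which are not independent replicates.

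The share of called probe sets near the insertions could not be told from that elsewhere. Among loci whose number lies within 5000 of AT2G22780 or AT5G09660 on the same chromosome, 15 of 583 tested probe sets (2.57%) were called, against 189 of 6675 elsewhere (2.83%). The odds ratio was 0.906 (95% interval 0.494 to 1.55, Fisher's exact test, two-sided p = 0.896). Among the 10 largest named increases and decreases, AT2G21820 (log2 fold change 2.01) and AT2G17850 (−2.05) lie within this distance of AT2G22780. Whether the change of a single gene there is linked to an insertion was not tested. Without the filter on dim probe sets the odds ratio was 2.01 and passed, and the ratio lay above 1 without the intensity trend, among probe sets naming 1 gene and without any 1 array other than wild-type replicate 1.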

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

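Alternatives concerning the 3 lists added later, and genes named after their values were seen, were chosen after seeing the data. All others were planned, but those for the disrupted genes gave no value, and the seed list kept too few members for a test under the stricter filter. Where a cause is not given below, the cause was not tested. All 516 called probe sets kept their direction in every refit that left out 1 array, and all that were tested did so under quantile normalization (515) and median centring (516). They were called on these same arrays, so a kept direction was likely beforehand. With 1 array left out, 257 to 451 of the 516 were called again. Over named genes, 1221 values kept direction and side of the threshold, 25 lost the call, 14 gained it and 32 turned sign, and for list medians 128 kept both, 11 turned sign and 1 gained the call. Counts of calls were 474 without a pseudocount, 532 with it doubled, 460 under quantile normalization and 538 with robust eBayes. Without the filter, which adds dim probe sets to the test, 228 were called (127 higher, 101 lower), 190 of them shared, the odds ratio near the disrupted loci was 2.01 (Fisher's exact p = 0.021) and the mitochondria-encoded median 0.012. The stricter filter tests fewer probe sets and gave 68 of at least 2-fold. Median centring gave 436 lower. Without the intensity trend 325 were called, 134 lower, and the odds ratio was 1.09. Among probe sets naming 1 gene, which are fewer, 211 were called (93 higher, 118 lower, 57 of at least 2-fold), with an odds ratio of 1.05. Ordinary t statistics called 12, 9 of them shared, with 1914 at an unadjusted p under 0.05. Of the 6 planned lists tested, camera with an estimated correlation called 0 and fry 2. Under quantile normalization the sugar starvation median was −0.075, ICL 0.049 and PRL −0.0011. Under median centring the tricarboxylic acid cycle median was −0.0048, sugar starvation −0.065, AIM1 −0.032, the KIN1 and KIN2 probe set −0.040, CP1 −0.021, AT4G14090 −0.030, PRL −0.031 and EXPA18 −0.031.

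With 1 array left out, 274 to 702 probe sets were called (135 to 361 higher, 134 to 341 lower), namely 343, 274 and 321 without mutant replicate 1, 2 and 3 and 702, 346 and 284 without wild-type replicate 1, 2 and 3. The odds ratio ranged from 0.967 to 1.52. Medians ranged from −0.019 to 0.019 for gibberellin and from −0.017 to 0.033 for sugar starvation genes. Genes whose sign turned ranged as follows, all without a call: OPCL1 −0.17 to 0.34, AIM1 −0.053 to 0.11, ICL −0.14 to 0.015, the KIN1 and KIN2 probe set −0.11 to 0.12, CP1 −0.039 to 0.20, GID1B −0.15 to 0.072, GID1C −0.070 to 0.026, ETFQO −0.34 to 0.0080, AT4G14090 −0.10 to 0.13, BIGYIN −0.0089 to 0.22, PRL −0.080 to 0.17 and EXPA18 −0.043 to 0.18. With the replicate number as a block, 686 were called (514 shared), and PPDK, DFR, UF3GT and PSBY passed. Deviations of same-numbered arrays correlated at 0.037, 0.174 and 0.135, and each array correlated best with its own number. This is a hint from the data and not from the design. Whether the numbers pair the samples stays open, and the main fit has no block. Signals near background limit dim transcripts, for which the fold depends on the pseudocount, as for M17.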

Other observations

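The lists in this part, the genes named in it, and the tests of scaling, of single arrays, of probe sets within 1 range of signal and of the choice of the hypoxia list were chosen after the data were seen. The tests of developmental stage, of RNA quality and of other splits were set before their results were. An SE over members is the SD over members divided by the square root of their number, which counts members as independent. They share the same 6 arrays. Estimated correlations were 0.42 for nuclear photosynthesis, 0.22 for plastid-encoded, 0.17 for mitochondria-encoded and 0.063 for the 14 remaining hypoxia members. These SEs therefore understate the error and do not measure the spread between samples.

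Transcripts encoded in the plastid genome were lower in the double mutant. Of 62 tested, 34 were lower, 0 higher and 28 did not pass in limma, 53 were lower when adjusted over the list alone, and all 62 had negative changes, with a median log2 fold change of −0.62. The gene of a photosystem II core protein, psbA, changed by −1.27 (SE 0.11, adjusted p = 1.96e-06), psaA of photosystem I by −1.07 (SE 0.17) and rbcL, the gene of the large rubisco subunit, by −1.03 (SE 0.18). Camera with an estimated correlation gave an adjusted p = 0.014. A pair of nuclear genes for chloroplast proteins, NdhS at −0.78 (SE 0.16) and LPA2 at −0.59 (SE 0.12), was also lower, and such genes outside the lists were not tested as a group. The calls of rbcL and NdhS were lost without the filter on dim probe sets, and that of NdhS also without wild-type replicate 3 (−0.71). The control probe set for 5S ribosomal RNA was lower in the same mutant arrays, with a signal of 11.0 ± 1.08 against 29.8 ± 3.15 (SD, n = 3 each, limma adjusted p = 0.036 over the 64 controls). The control for 25S ribosomal RNA did not pass, with a mean signal of 395 in the mutant, from 68.1 to 681 between arrays, against 240 in the wild type (log2 fold change 0.23, limma adjusted p = 0.95).

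Of the genes known to respond to low oxygen, some were lower in the mutant beyond the 10 largest decreases among probe sets that name 1 gene. Of 24 tested loci of a list written once AT3G10040 and CML38 had been seen, 17 were lower, 0 higher and 7 did not pass, and 20 were lower when adjusted over the list alone. The median was −1.24, but the list holds all 10 of those decreases, so its count and median are partly set by the genes that prompted it. The other 14 loci had a median of −0.59, with 7 lower and 7 not passing, of which AT1G19530 (0.36) and AT3G10020 (0.23) had positive changes, and gave p = 0.00588 in limma's camera with an estimated correlation. These 14 come from the same list, so this p does not test the choice of the list. AT3G03270 was 2.28-fold lower (−1.19, SE 0.15, adjusted p = 0.000211), while PDC2, a pyruvate decarboxylase gene, did not pass at −0.29 (SE 0.12, adjusted p = 0.22). Raised genes outside the fixed lists included the dehydrin gene LTI30 at 1.17 (SE 0.15), GSTU22, a glutathione transferase gene, at 1.44 (SE 0.12) and the glycosyltransferase gene UGT73B4 at 1.05 (SE 0.23). The call of UGT73B4 was lost without the filter and without mutant replicate 1 (1.08), mutant replicate 2 (0.88) or wild-type replicate 3 (1.06).

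The rise of seed storage and maturation transcripts did not depend on scaling or on 1 array. Its median was 1.66 under quantile normalization and at least 1.46 with any 1 array left out, against 1.73, which argues against either as the whole cause. A candidate explanation is that mutant seeds were at an earlier developmental stage when harvested, since late embryo transcripts decline and photosynthetic transcripts build up as seedlings emerge. The nuclear photosynthesis list, tested for this, had a median of −0.49 (SE over members 0.0542), consistent with that hypothesis. The labels give growth stage 0.7 for all 6 samples, so a difference in stage would have to lie within that label. ICL did not differ past the threshold, and few markers of dividing cells were measured. A direct effect of the missing enzyme on the seed storage and maturation transcripts, at equal stage, stays open.

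The fall of plastid-encoded transcripts might come from RNA quality or from labelling of transcripts without stable poly(A) tails, and the lower 5S ribosomal RNA control (log2 fold change −0.92) goes with that. Mitochondria-encoded transcripts share the property, and 8 tested probe sets had a median of −0.12 (SE over members 0.0556), with 0 called in limma and 0 at an unadjusted p under 0.05, while the 26 plastid-encoded probe sets within their range of signal, though brighter (median level 6.86 against 5.97), had a median of −0.72 (SE over members 0.0473), which argues against it as the whole cause. The mitochondria-encoded probe sets are few and mostly dim, and their list passed camera without mutant replicate 2 (−0.14), so a contribution stays open. Mutant signals of the 5S control (12.2, 10.2 and 10.6) lay close to the pseudocount of 10. The 25S ribosomal RNA control had a positive change (0.23) and did not pass (limma adjusted p = 0.95), so the 2 controls do not point 1 way. Under quantile normalization the plastid-encoded median was −0.63, which argues against scaling. Later plastid development in the mutant, a hypothesis not tested separately, and any difference in harvest between the genotypes, which the labels do not record, also stay open.

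The fall of hypoxia-responsive transcripts could reflect a list chosen for its most changed members. The 14 loci outside the 10 largest named decreases had a median of −0.59 (SE over members 0.140). The fall was thus not confined to those 10. All 14 belong to a list written after the data were seen, so this cannot tell whether they too were chosen for their change. Under quantile normalization the list's median was −1.28, which argues against scaling. A weaker low-oxygen response in the mutant seeds is a hypothesis for which no measurement was made, and the oxygen supply during growth or harvest is confounded with genotype if it differed.

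The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 516 probe sets and the highest of the other 9 called 0 in limma, with 210 to 805 at an unadjusted p under 0.05 against 2356, so 1 of the 10 splits called as many. For gene lists with a preset correlation, the real split called 3, and the highest of the others also 3, so 3 of the 10 splits called as many. Each of the other 9 splits mixes the genotypes within its groups. Such a split keeps part of the genotype difference between its groups and adds the rest to the spread within them. The counts of these 9 splits, of probe sets and of lists, therefore do not show what arrays without a genotype difference would give.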
